A study of Mus musculus with 6 samples.

How the data were processed

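The series holds 6 RNA libraries of cultured adult mouse neural stem cells, 3 treated with DMSO and 3 with PluriSIn#2. Samples were grouped by their titles. The treatment field of treated replicates 2 and 3 carries other numbers after PluriSIn than their titles do, so a fit with treated replicate 1 alone was added after seeing the data. Total RNA was extracted with a column kit and sequenced on an Illumina instrument, per the labels.

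Per the submitters' processing notes, STAR, HTSeq, DESeq and the genome build mm10 were used. Their versions, the annotation, the strand setting and the filters are not given in the sources used here. The deposited count table gives whole-number read counts per gene symbol for each library, not normalized, and its name refers to HTSeq, a counter of reads per gene. The deposited FPKM table gives expression normalized by the authors for gene length and sequencing depth. For 92.7% of the 10194 genes with at least 100 counts in every library, the gene length implied by the FPKM and the counts was equal between groups within 1%, and for 77 genes it differed by over 10%. The same table carries the authors' deposited log2 fold changes of PluriSIn#2 over DMSO, whose sign was checked against their FPKM. It also carries the authors' deposited p-values, raw and adjusted, from their own test. There, 25 gene names had turned into dates, and those entries were left out of every use of it.

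The count table lists 24421 genes, of which 19218 had a read and 14417 passed edgeR's filterByExpr with default settings. The 4801 other genes with a read were not tested in the main analysis. The sources used here name no molecular identifiers, so floors cover counting error only. Libraries held between 16670962 and 19241869 counts, and genes with few reads are measured in coarse steps. Gene symbols were matched to GENCODE mouse release M21 on GRCm38, the same build as mm10, for spans, exonic lengths and coordinates, and 13878 of the tested genes (96.3%) matched. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be mixed.

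Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors ran from 0.975 to 0.978 in DMSO and from 1.02 to 1.03 in PluriSIn#2. The test was the quasi-likelihood F test of edgeR (glmQLFit, glmQLFTest) on all 6 libraries with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CPM values use library totals times TMM factors, and means are given ± SD over 3 libraries. Log2 fold changes are the fitted values of edgeR with their standard errors. For a gene with no read in a group, a fold was computed against a floor of 3 counts over that group. Similarity of libraries was described on log2 CPM with a prior count of 2. A chi-square statistic on genes with at least 20 counts, per degree of freedom, was between 1.56 and 2.22 for pairs of replicates, so no library was a copy of another within sampling noise, and between 201 and 215 for pairs across groups.

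The 42 gene lists, the test of each, the alternatives and the rule for named genes were fixed before the data were examined. They cover topoisomerases, ubiquitin-specific proteases, the cell cycle, DNA repair, p53, apoptosis, senescence, stem cell states, signalling, metabolism, ribosomes, stress responses and other cell types. Lists with at least 5 measured members were tested with camera from limma 3.58.1 in the edgeR fit, with a preset correlation of 0.01, adjusted over lists, then again with an estimated correlation and with fry. Of the 42 lists, the mitochondrially encoded and the erythroid genes had fewer than 5 measured members and were not tested. A few genes that the rule or the lists would name are not reported here. The rule named Top2a, Top2b, Top1 and Usp37 always. It added the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and a proper gene name. It also took the 2 members with the smallest p in the direction of each of the 12 lists with the smallest camera p, and the most abundant member of each list of another cell type. A further 10 lists were chosen after a first look at the genes with the largest changes.

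The script was tested on a simulated PluriSIn#2 against DMSO comparison. Counts were drawn from the DMSO means and the real library sizes, with 50 genes changed by each of 4 fold sizes. All other genes were left unchanged, unlike the real comparison, in which most genes were called. Over 13738 genes, edgeR recovered 64% of genes changed 1.2-fold, 90% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 12 unchanged genes called. DESeq2, over 14417 genes, recovered 52%, 84%, 78% and 96% with 1 unchanged gene called. Run on log2(CPM + 1) rather than FPKM, limma recovered 64%, 90%, 86% and 90% over 13037 genes, with 12 unchanged genes called. In a simulated list test, the list shifted by 0.3 on the log2 scale was called and 0 of the other lists tested were called by camera. Genes outside the shifted list were left unchanged there, so neither simulation tests scaling or camera where most genes change. Each gene was also drawn independently, so the list simulation does not test camera where members of a list are correlated.

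Alternatives were median-of-ratios factors, library totals alone, no filter beyond a read, a filter at 1 CPM in 3 libraries, a replicate block, the DESeq2 1.42.0 Wald test, each library left out in turn, and limma on log2(FPKM + 1) with a minimum mean FPKM of 1, on log2(FPKM + 0.1), and on log2(FPKM + 1) without that filter. Fold changes on the log2(FPKM + pseudocount) scale understate the changes of low genes. A threshold of 0.01 and the 500 genes with the highest variance were tried as well.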

Results

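RNA sequencing measured gene expression in primary neural stem cells grown from the subventricular zone of C57BL/6 mice at postnatal day 60. The subventricular zone is the lining of the lateral ventricles where adult mice keep making neurons. The cells were cultured with EGF and FGF2 at 20 ng/ml and received 20 µM PluriSIn#2, which the labels describe as a topoisomerase IIA inhibitor, or its solvent DMSO. Treatment lasted 3 days, with medium replaced at 24 h. There were 3 libraries per group. Total counts were 18289463, 18186070 and 19241869 in DMSO replicates 1, 2 and 3, and 17292796, 17827158 and 16670962 in PluriSIn#2 replicates 1, 2 and 3. A read was found for between 16909 and 16987 genes in the DMSO libraries and for between 17300 and 17421 genes in the treated ones. The most abundant gene, Ckb, took at most 0.663% of the counts of any library.

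The comparison of PluriSIn#2 with DMSO asks which transcripts of adult neural stem cells change when topoisomerase IIA is inhibited. Top2a, the gene of the targeted enzyme and itself a marker of dividing cells, stood at 854, 888 and 893 CPM (counts scaled to a common library size) in the 3 DMSO libraries and at 5.59, 7.46 and 4.98 CPM in the 3 PluriSIn#2 libraries. Genes of DNA replication, mitosis and chromosome structure were almost all lower in the treated cells, and most genes of cholesterol synthesis, ribosome biogenesis and oligodendrocyte precursors were lower too. Targets of p53, genes of quiescent stem cells and astrocytes, lysosomal genes and senescence-associated secreted factors were mostly higher. Most measured markers of macrophages, fibroblasts and blood vessels also rose, although the list calls of macrophage genes (adjusted p = 0.0666 with an estimated correlation, camera) and endothelial genes (adjusted p = 0.107 with an estimated correlation) did not hold.

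The fall of Top2a was 145-fold, from 878 ± 21.2 to 6.01 ± 1.29 CPM (mean ± SD, n = 3 per group). Its log2 fold change was -7.18 (SE 0.045) with an adjusted p of 2.35e-102 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which also gave the other adjusted p-values for single genes here. Top2a lies on chromosome 11 from 98992943 to 99024189 on the minus strand (coordinates here are of GRCm38, the build also called mm10, from the GENCODE annotation). Top2b, the other type IIA topoisomerase, fell from 338 ± 7.71 to 217 ± 4.54 CPM (log2 fold change -0.64, SE 0.027, edgeR adjusted p = 4.62e-38). It lies on chromosome 14 from 16365179 to 16435462. Top1, the type IB enzyme on chromosome 2 from 160645888 to 160722764, fell from 312 ± 4.67 to 153 ± 3.86 CPM (log2 fold change -1.02, SE 0.028, edgeR adjusted p = 1.5e-51). Of 13 measured topoisomerase and partner genes 11 fell, among them Topbp1 (-2.64) and Rmi2 (-4.54), and 2 rose, Top3b (0.73) and the mitochondrial Top1mt (1.14). The camera adjusted p of the list was 4.59e-06, and the adjusted p = 0.0906 with an estimated correlation.

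Usp37, a deubiquitinase gene named in the title of the series, fell from 85.0 ± 3.32 to 28.8 ± 1.04 CPM (log2 fold change -1.56, SE 0.051, edgeR adjusted p = 2.15e-46). It was lower in each of the 3 treated libraries than in any DMSO library (82.0, 88.6 and 84.5 CPM). The gene spans 109 kb of chromosome 1, from 74435511 to 74544284 on the minus strand. Because the study chose Usp37, possibly from these libraries, its fall is not independent evidence. Among 46 measured ubiquitin-specific proteases 30 fell, 10 rose and 6 were not called. Usp44 (-5.10), Usp1 (-2.14) and Usp13 (-1.60) fell by more than Usp37, while Usp35 (1.16) and Usp2 (0.94) rose. The family's median log2 fold change was -0.29 (camera adjusted p = 0.0439, and adjusted p = 0.0983 with an estimated correlation). Scaling by library totals alone ended this call (camera adjusted p = 0.0569), as did a filter at 1 CPM (0.0544).

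**Figure D1:**
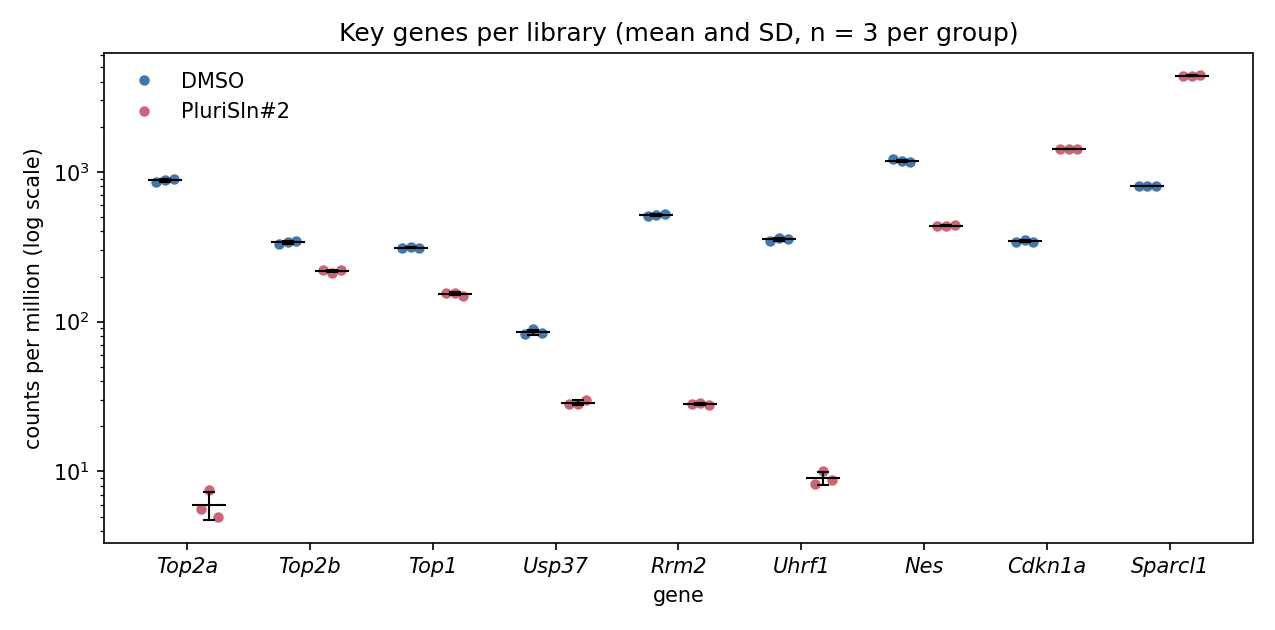
CPM on a log scale for key genes in each of the 6 libraries, with 3 DMSO (blue) and 3 PluriSIn#2 (red) points per gene and black bars for the mean and SD. Top2a drops from a mean of 878 to 6.01 CPM, Usp37 from 85.0 to 28.8, and Cdkn1a climbs from 344 to 1419.

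The treatment changed most of the transcriptome. Of 14417 genes tested, 6015 were higher and 5900 lower in PluriSIn#2, 82.6% in all, and 2502 were not called. At least 2-fold changes were found for 2353 higher and 1687 lower genes. The 3 DMSO and 3 treated values did not overlap for 11927 genes (82.7%, where chance gives 10%). Correlations of log2 CPM were at least 0.994 within groups and at most 0.880 between them, and the first principal component, which parted the groups, held 94.6% of the variance. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

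The largest falls among genes averaging at least 5 CPM were in mitotic genes and 1 oligodendrocyte-lineage gene. Casc5, a kinetochore scaffold, fell from 89.4 ± 2.59 to 0.224 ± 0.259 CPM (log2 fold change -8.58, SE 0.13). Mki67, which encodes the proliferation antigen Ki-67, fell from 1020 ± 6.25 to 3.19 ± 0.204 CPM (-8.32, SE 0.045). Depdc1a (-8.36), the checkpoint kinase gene Bub1 (-7.86) and the kinetochore gene Ska1 (-7.78) fell in the same range. Gpr17, a receptor of committed oligodendrocyte precursors, fell from 33.2 ± 0.648 to 0.130 ± 0.0818 CPM (-7.90, SE 0.19). The treated values of Depdc1a, Ska1, Gpr17 and Casc5 rest on 4, 5, 7 and 12 reads over the 3 libraries. These 6 genes had edgeR adjusted p-values of 9.12e-50 or lower.

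The largest rises, again among genes averaging at least 5 CPM, were in genes that DMSO libraries barely contained. Trem2, a receptor of microglia and macrophages, had 0 reads in the DMSO libraries and 543 in the treated ones, which made it at least 186-fold higher against a floor of 3 counts over the DMSO group. The macrophage elastase gene Mmp12 rose from 0.108 to 37.5 CPM (log2 fold change 8.32, SE 0.20). Ttr, which encodes the thyroid hormone carrier transthyretin made by choroid plexus, rose from 1.89 ± 0.408 to 501 ± 8.57 CPM (8.04, SE 0.057). The endothelial cadherin gene Cdh5 (6.93), the peptidase gene Anpep (6.92) and the proteoglycan gene Dcn (6.85) followed. Apart from Ttr, the DMSO values of these genes rest on at most 7 reads over 3 libraries. These 6 genes had edgeR adjusted p-values of 9.16e-38 or lower.

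Across 42 gene lists fixed before the data were examined, 40 had at least 5 measured members and were tested with camera. At an adjusted p under 0.05, 12 were called higher and 14 lower in PluriSIn#2. Of these 26 calls, 16 held when the correlation between genes was estimated from the data, and 10 did not. For each of the 40 lists, the counts of members that rose and fell adjusted over the list alone equalled those over all genes tested. Members quoted as examples beyond the fixed rule for named genes were chosen after their values were seen.

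Cell cycle genes fell together. Of 54 measured G2 and M phase genes 53 fell, with a median log2 fold change of -5.57 (camera adjusted p = 4.99e-119), including Cdk1 (-6.03), Ccnb1 (-6.90) and Aurkb (-7.39). The exception, Psrc1, is also a p53 target and rose from 141 to 283 CPM. All 41 S-phase genes fell (median -3.67, camera adjusted p = 5.02e-61). Among them, the ribonucleotide reductase gene Rrm2 fell from 515 ± 7.02 to 28.1 ± 0.491 CPM, the replicative helicase gene Mcm2 from 298 ± 4.69 to 17.2 ± 1.04 CPM, and Uhrf1, which guides maintenance DNA methylation, from 353 ± 9.94 to 9.02 ± 0.961 CPM. All 36 condensin, cohesin and chromatin genes fell (median -1.49, camera adjusted p = 1.28e-49), as shown by Ncapg (-7.72), Ezh2 (-2.67) and Dnmt1 (-2.41). Of these 9 are also in other fixed lists, among them Mki67 and Uhrf1. Of 26 G1 cyclins, kinases and inhibitors 20 fell and 6 rose (median -1.39, camera adjusted p = 4.87e-06). The G1 activators E2f2 (-5.61) and Ccne1 (-2.72) fell, as did the inhibitors Cdkn2a (-2.65) and Cdkn2c (-3.28), while the inhibitor Cdkn1a rose. Among 34 genes of homologous recombination and Fanconi anaemia repair, 32 fell and 2 were not called (median -2.29, camera adjusted p = 5.4e-12), with Brca1 at -5.50 and Fancd2 at -5.27. Of 15 end-joining genes 11 fell and 4 were not called (median -0.46, camera adjusted p = 0.00335, and adjusted p = 0.0666 with an estimated correlation).

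Targets of p53 rose. Of 45 measured, 39 rose, 3 fell and 3 were not called (median 1.204, camera adjusted p = 8.46e-22). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 344 ± 4.82 to 1419 ± 2.66 CPM (log2 fold change 2.05, SE 0.021). Abhd4 rose from 259 ± 4.28 to 973 ± 7.19 CPM (1.91, SE 0.023), and Mdm2 (1.37), Ccng1 (1.64) and Fas (3.17) rose with it. The 3 that fell were Ckap2 (-1.49) and Gtse1 (-0.59), both also mitotic genes, and Tigar (-0.24). Senescence-associated secreted factors also rose, with 23 of 32 higher, 4 lower and 5 not called (median 1.25, camera adjusted p = 1.79e-07). Matrix metalloproteinases Mmp3 (6.78), Mmp12 and Mmp13 (5.47) led them, and Spp1 rose from 32.5 to 456 CPM (3.81), in the same libraries in which macrophage and fibroblast transcripts were higher. The chemokines Cxcl1 (-2.07), Cxcl2 (-2.83) and Cxcl10 (-2.49) fell. Apoptosis effectors were divided, with 11 of 27 higher and 10 lower, a median of 0.06 and a mean of -0.05 (camera adjusted p = 0.656, direction higher). The BH3-only genes Bbc3 (1.81) and Pmaip1 (2.15), which are also p53 targets, rose, and Birc5 (-5.39), also a mitotic gene, fell.

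Genes of the quiescent stem cell and astrocyte state rose while those of activated progenitors fell. Of 40 quiescent neural stem cell and astrocyte genes 35 rose and 5 fell (median 1.39, camera adjusted p = 3.7e-32). The lipid carrier gene Apoe rose from 260 ± 7.40 to 5486 ± 135 CPM and the matrix gene Sparcl1 from 803 ± 4.74 to 4371 ± 32.7 CPM. Gfap (2.84), Clu (2.53) and Gja1 (2.09) rose as well. Apoe and Clu are also made by macrophages and other cells, whose marker transcripts rose in the same libraries. The 5 that fell were Thbs4 (-5.19), Hes5 (-2.33), Fabp7 (-1.23), Prom1 (-0.32) and Lrig1 (-0.15). Of 28 activated stem cell and transit-amplifying progenitor genes 22 fell, 4 rose and 2 were not called (median -0.92, camera adjusted p = 7.2e-08). Of these genes 15 are also in other fixed lists, among them the S-phase gene Mcm2 and the G1 genes Ccnd1 and Cdk4. Their fall is thus not separate from that of cell cycle genes. Nes, the intermediate filament gene nestin, fell from 1187 ± 20.4 to 437 ± 3.21 CPM, and Egfr (-1.31), Sox11 (-1.52) and Dll3 (-4.36) fell too.

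Among oligodendrocyte and neuronal lists, only that of oligodendrocyte precursors was called with an estimated correlation (camera adjusted p = 0.0217). Of 24 oligodendrocyte precursor genes 21 fell, 2 rose and 1 was not called (median -0.99, camera adjusted p = 1.5e-05), with Sox10 at -4.77, Bcas1 at -4.45 and Pdgfra at -3.54. The most abundant member, Ptprz1, rose slightly, from 2771 ± 24.8 to 2933 ± 38.9 CPM. Myelinating oligodendrocyte genes were not called, with 6 of 15 higher and 7 lower (median 0.03, mean -0.63, camera adjusted p = 0.823, direction lower), and their most abundant member, Car2, rose (1.03). This median changed sign with the libraries and the filter: it was -0.27 without DMSO replicate 1, -0.31 without DMSO replicate 3, -0.30 and -0.28 without PluriSIn#2 replicates 1 and 3, and -0.59 without a filter on low counts. Of 45 neuroblast and neuronal genes 29 rose and 9 fell (median 0.63), and the list was not called (camera adjusted p = 0.648). Slc32a1 (2.37), Slc17a7 (2.44) and Gad1 (1.34) rose, and Map2 (-1.22), Gap43 (-1.12) and Dpysl3 (-1.27) fell. The neuroblast genes Dcx (19.9 and 17.9 CPM in DMSO and PluriSIn#2) and Tubb3 (20.8 and 22.6 CPM) were not called. Of 35 targets of the neuronal repressor REST 22 rose, 7 fell and 6 were not called (median 0.56, camera adjusted p = 0.0291, and adjusted p = 0.165 with an estimated correlation). Scg2 (2.57) and Vgf (1.76) were among the risers. Rest itself was not called, at 43.7 and 40.8 CPM.

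Most measured markers of macrophages, mural cells, endothelium and ependyma rose. Members with few DMSO reads were measured only where treated counts were high enough for the filter, which favours risers in these counts. Without a filter on low counts the medians were 5.10 for macrophage, 2.24 for pericyte and fibroblast, 1.92 for endothelial and 1.63 for ependymal genes. Of 21 microglia and macrophage genes 19 rose, 1 fell and 1 was not called (median 5.61, camera adjusted p = 4.19e-06, and adjusted p = 0.0666 with an estimated correlation). Lyz2 rose from 1.26 to 81.8 CPM, Ctss from 0.335 to 21.9 CPM and C1qc from 0.183 to 10.2 CPM. The most abundant member, Sall1, fell by 0.21 on the log2 scale from 145 CPM, and P2ry12 was not called (1.24 and 1.29 CPM). Of 19 pericyte, smooth muscle and fibroblast genes 14 rose and 3 fell (median 2.91, camera adjusted p = 6.35e-05), with Col3a1 at 6.60, Col1a2 at 5.89 and the most abundant, Fn1, at 1.38. Of 16 endothelial genes 14 rose and 2 were not called (median 1.92, camera adjusted p = 0.0187, and adjusted p = 0.107 with an estimated correlation), among them Slc2a1 (0.84), the most abundant. Of 26 ependymal and multiciliated cell genes 21 rose, 1 fell and 4 were not called (median 1.74, camera adjusted p = 0.0308, and adjusted p = 0.0983 with an estimated correlation). Foxj1, the regulator of motile cilia, rose from 34.1 ± 0.431 to 144 ± 1.26 CPM, and scaling by library totals ended the ependymal call (camera adjusted p = 0.0505).

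**Figure D2:**
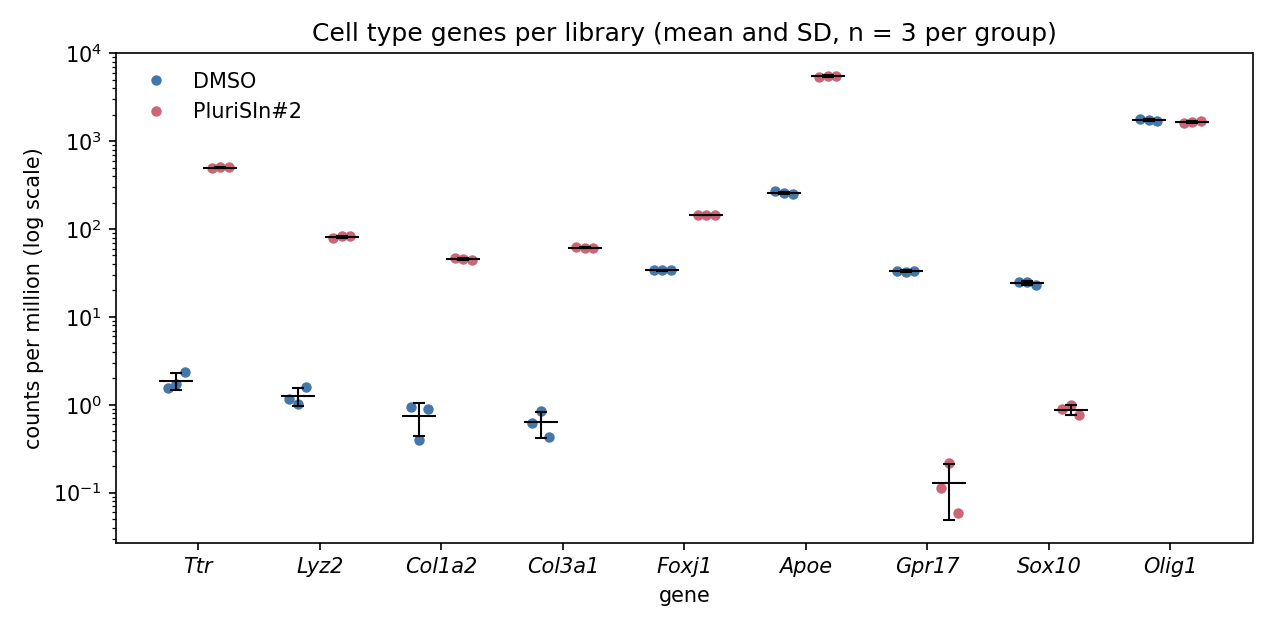
CPM on a log scale for genes of several cell types in each of the 6 libraries, with 3 DMSO (blue) and 3 PluriSIn#2 (red) points per gene and black bars for the mean and SD. Ttr reaches a mean of 501 CPM and Lyz2 81.8 CPM in the treated libraries, from 1.89 and 1.26 CPM in DMSO, while Gpr17 drops to 0.130 CPM.

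Metabolic genes split by pathway. All 25 cholesterol synthesis genes fell (median -1.57, camera adjusted p = 2.93e-23). Hmgcs1, which makes the precursor of mevalonate, fell from 1217 ± 21.1 to 362 ± 13.4 CPM, and Insig1 fell from 369 ± 8.73 to 77.5 ± 2.56 CPM. Of 24 fatty acid synthesis genes 12 fell, 8 rose and 4 were not called (median -0.09, camera adjusted p = 0.014, and adjusted p = 0.0879 with an estimated correlation). Elovl6 (-1.70) and Scd1 (-1.34) fell and Elovl7 (1.67) rose. The fatty acid call also ended without PluriSIn#2 replicate 3 (camera adjusted p = 0.0555) and without a filter on low counts (0.0693). All 45 nuclear-encoded respiratory chain genes rose (median 0.63, camera adjusted p = 1.28e-13, and adjusted p = 0.0983 with an estimated correlation). Cox6a1 rose from 392 ± 17.4 to 929 ± 35.4 CPM and Cox4i1 from 484 ± 3.80 to 972 ± 10.3 CPM. Mitochondrially encoded genes were not analysed here.

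Genes for making ribosomes fell. Of 36 ribosome biogenesis genes 35 fell and 1, Rrp1, rose (median -0.85, camera adjusted p = 1.39e-07). The nucleolar genes Ncl (996 ± 8.08 to 482 ± 12.7 CPM) and Npm1 (345 ± 6.31 to 147 ± 3.15 CPM) were among them. Of 75 ribosomal protein genes 66 fell, 2 rose and 7 were not called (median -0.66, camera adjusted p = 1.54e-07, and adjusted p = 0.0906 with an estimated correlation). Counts of ribosomal protein genes are uncertain, since their many processed pseudogenes can share or take their reads.

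Genes of lysosomes, detoxification and matrix rose. Of 38 lysosome and autophagy genes 34 rose, 1 fell and 3 were not called (median 0.59, camera adjusted p = 1.55e-10). The protease genes Ctsd (379 ± 0.509 to 1727 ± 25.7 CPM) and Ctsb (256 ± 7.20 to 1096 ± 2.17 CPM) rose furthest, and both are also abundant in macrophages, whose markers rose alongside. Of 26 targets of the aryl hydrocarbon receptor and NRF2, 20 rose, 4 fell and 2 were not called (median 0.87, camera adjusted p = 1.15e-08). The glutathione transferase gene Gstm1 rose from 210 ± 1.59 to 1711 ± 9.14 CPM and the haem oxygenase gene Hmox1 from 78.0 ± 2.08 to 616 ± 10.8 CPM, while Ahrr fell (-2.80). Of 47 extracellular matrix and adhesion genes 30 rose, 12 fell and 5 were not called (median 0.73, camera adjusted p = 6.28e-06). Col4a1 (2.36), Col6a2 (4.44) and Sparc (2.32) rose, as did the fibroblast markers, and Tnc (-2.14), a matrix protein of progenitors, fell.

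Signalling and stress lists were not called. Camera adjusted p-values were 0.0568 for EGF, FGF and MAPK response genes (20 of 33 rose, 10 fell), 0.0664 for the unfolded protein and integrated stress response (10 of 35 rose, 22 fell), 0.136 for hypoxia and glycolysis (18 of 34 rose, 9 fell), and 0.14 for BMP and TGF-beta genes (22 of 33 rose, 6 fell). They were 0.225 for stem cell transcription factors (12 of 29 rose, 15 fell), 0.323 for Notch (11 of 30 rose, 15 fell), 0.384 for Wnt (11 of 37 rose, 21 fell) and 0.434 for Hedgehog genes (4 of 14 rose, 9 fell). Single members still moved, such as Fos (1.80), Asns (-2.31), Tgfb1 (3.58), Sox2 (-0.58), Mfng (-4.31) and Lgr5 (-2.86). Only 9 of the 30 listed canonical histone genes were measured, so the list does not speak for the rest. The measured histone genes had a median of -0.41 and a mean of -0.78 although camera put their direction as higher (3 of 9 rose, 4 fell, camera adjusted p = 0.505). Their median was 0.24 without DMSO replicate 1 and 0.10 without DMSO replicate 3, against -0.62 without PluriSIn#2 replicate 1, so it gives no stable direction. Interferon-stimulated genes had a median of -0.05 and a mean of 0.13 (11 of 32 rose, 10 fell, camera adjusted p = 0.579, direction higher), and the median was 0.08 without DMSO replicate 2. Heat shock genes had a median of -0.15 and a mean of 0.14 (8 of 22 rose, 12 fell, camera adjusted p = 0.665, direction lower).

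**Figure D3:**
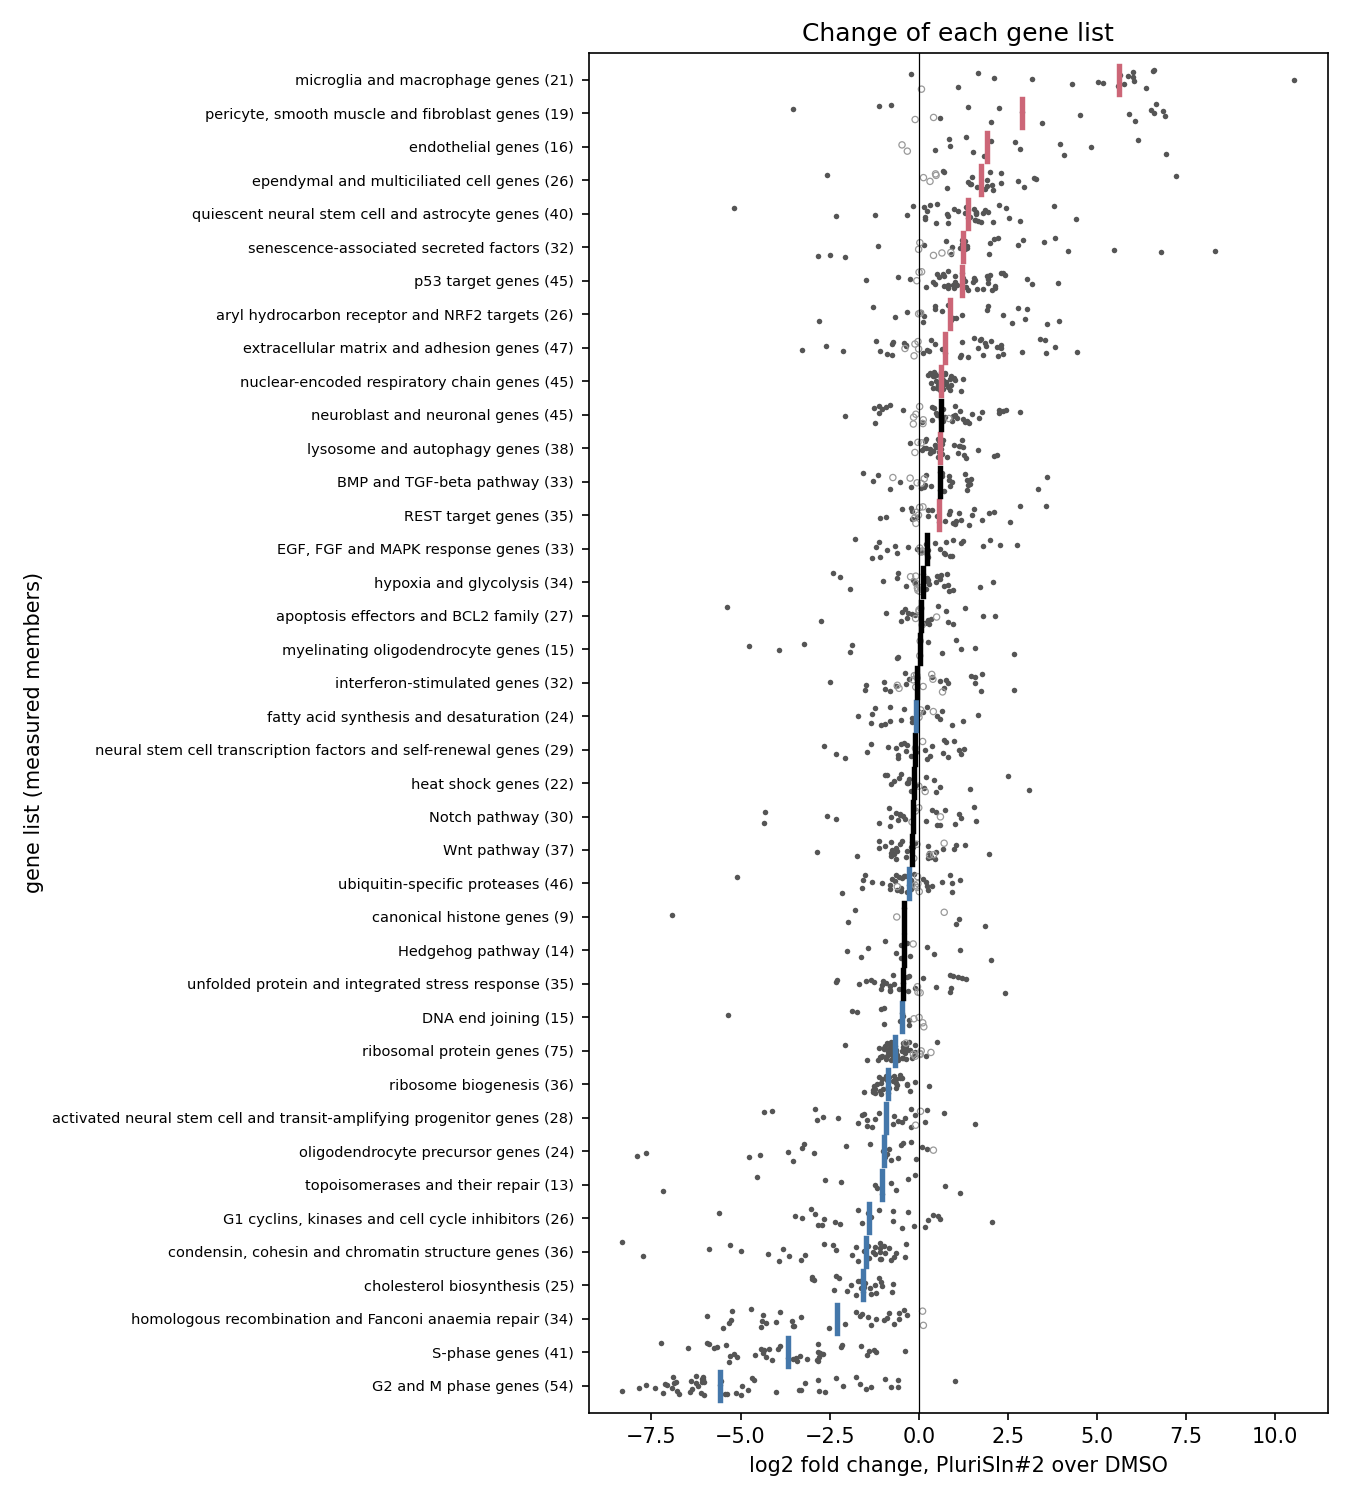
Log2 fold change of every measured member (filled dots, called; open dots, not called) of each tested gene list, with the list median as a bar coloured red (called higher), blue (called lower) or black (not called). G2 and M phase genes lie lowest, with a median of -5.57, and microglia and macrophage genes highest, with a median of 5.61.

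The authors' deposited table of their own test called 5827 genes higher and 5662 lower at an adjusted p under 0.05. The DESeq2 Wald test run here called the same total, 11489 genes, 50.7% of them higher. Both rest on the same libraries as the main fit, so neither is an independent check of it. The authors' deposited table shared 14395 of the genes tested here. Of these, 11054 were called in both with the same direction and 0 were called in both with opposite directions (Pearson r of log2 fold changes 0.9997, across genes, which are not independent replicates). The authors' deposited table gave Top2a a log2 fold change of -7.19, Usp37 -1.57, Top1 -1.03 and Top2b -0.64.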

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

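Only the fit with treated replicate 1 alone was chosen after seeing the data. The numbers of genes called higher and lower stayed within 1.5 times their main values in every alternative: between 10494 and 12507 genes were called in all under other scalings, filters, tools and left-out libraries, against 11915, and treated replicate 1 alone, whose spread was taken from the DMSO libraries, called 10943. Library totals alone shared 11399 of the calls, median-of-ratios factors 11891 and the DESeq2 test 11070. Of the calls under library totals alone 54.8% were higher, against 50.5% in the main fit. These scalings moved the median gene by at most 0.07 on the log2 scale, so a larger shift between groups was not tested. Counts of at least 2-fold changes dropped on the compressed log2(FPKM + 1) scale, to 1238 higher and 1111 lower with the filter and 1301 higher without it. With an estimated correlation 7 lists were called higher and 9 lower, while fry, which does not compare a list with other genes, called all 40, 19 higher and 21 lower. On the 500 genes with the highest variance the lowest correlation within a group was 0.979 and the highest between groups -0.0592, as follows from choosing genes that differ. Named genes kept direction and side of the threshold in 626 comparisons and gained a call in 1. List tests kept theirs in 482 comparisons, with 15 calls lost and 22 gained, and EGF and MAPK response, BMP and TGF-beta and unfolded protein response lists passed under some of them. No named gene and no list called in both settings changed direction. The medians of myelinating oligodendrocyte, canonical histone, interferon-stimulated and fatty acid synthesis genes changed sign under some settings, and camera turned the direction of the histone list without a filter on low counts. With the replicate number as a block, 11851 genes were called, 5984 higher and 5867 lower. Same-numbered libraries did not deviate together (correlations of -0.064, -0.060 and -0.013), and by these deviations no library correlated best with its own number. This gives no sign of pairing by number. It cannot exclude pairing, since replicates differed by little more than counting noise. Depth limits fold changes of genes with few reads in a group, such as Trem2 and Mmp12 in DMSO.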

Other observations

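The 10 gene lists in the next paragraphs, the comparison of implied gene lengths, and the tests of a lower neural share, of 1 contaminated library, of Usp37 against S-phase genes and of normalization for respiratory chain and ribosomal protein genes were chosen only after the results they follow up were seen.

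In further lists, most genes of nucleotide synthesis, splicing and tRNA charging were lower in PluriSIn#2. Of the nucleotide synthesis genes 3, of the kinesins 5 and of the neurotransmitter receptors and channels 3 are also in the fixed lists. Of 29 nucleotide synthesis genes 27 fell and 2 rose (median -0.90, camera adjusted p = 6.52e-13), with Tk1 at -4.99 and Tyms at -3.41. Of 43 splicing factors 41 fell and 1, Rbfox2, rose (median -0.83, camera adjusted p = 6.52e-13), including Srsf1 (-1.57) and Hnrnpa2b1 (-1.11). Of 20 aminoacyl-tRNA synthetases 19 fell (median -0.59, camera adjusted p = 0.00014), and Dars rose. Of 31 proteasome subunits 29 fell and 2 were not called (median -0.39, camera adjusted p = 0.00393, and adjusted p = 0.271 with an estimated correlation). Of 35 kinesins, the motors of microtubules, 18 fell and 14 rose (median -0.19, camera adjusted p = 3.09e-08). Kif11 (-6.93) and Kif14 (-6.88) fell, and Kif5a (1.02) and Kif5c (0.88) rose. Neurotransmitter receptors and channels were not called (15 of 37 rose, 14 fell, median 0.05, camera adjusted p = 0.41), although the AMPA receptor genes Gria1 (2.20), Gria3 (1.47) and Gria4 (1.86) rose.

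Complement and MHC class I genes were higher, with 17 of 21 up and 1 down (median 1.19, camera adjusted p = 0.0139, and adjusted p = 0.071 with an estimated correlation), among them Tap2 (1.79) and B2m (0.71). Macrophage transcripts were higher in the same libraries. Of 22 leptomeningeal and mural fibroblast genes 17 rose and 4 fell (median 2.20), but the list was not called (camera adjusted p = 0.31). Aldh1a2 (7.41) and Col8a1 (3.75) rose, and Fbln2, the most abundant, fell from 666 to 55.8 CPM. A second macrophage list rose (28 of 31 measured members, 1 lower, camera adjusted p = 0.00106). Its median was 4.12, or 4.06 with the 2 members at 0 in DMSO set to their bound. Of 22 measured choroid plexus genes 19 rose (median 3.26, camera adjusted p = 5.7e-06).

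The rise of macrophage and fibroblast genes may come from more such cells in the treated cultures, from a loss of neural cells around them, or from neural cells that switched these genes on. A lower share of neural cells alone would raise non-neural types alike and stays open: the macrophage median exceeded that of fibroblast genes by 2.70, with overlapping bootstrap intervals (4.29 to 6.00 and 0.59 to 6.07), and that of endothelial genes by 3.69, without overlap (0.88 to 3.96). A single contaminated library is argued against by the median macrophage gene being raised at least 2-fold in all 3 treated libraries (4.25, 4.42 and 4.22 on the log2 scale over the DMSO mean, with 0.1 CPM added). These values do not bear on contamination of a culture, which the 3 libraries may share. More macrophages stay open, since 90.3% of the 31 measured members of the second list rose, out of 40 listed. The filter favours this share, as members with few DMSO reads were measured only where treated counts were high enough. The most abundant risers of the second list were Mpeg1 (28.7 CPM) and Plek (14.3 CPM), and Lyz2 stood at 81.8 CPM in the first. DMSO cultures already had 2 of the 21 genes of the first list and 2 of the 31 of the second above 10 CPM, and 1 gene of the first is shared with another fixed list.

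Whether Usp37 fell as genes of dividing cells do is not decided by its place among S-phase genes. Its log2 fold change (-1.56) lay inside that list, below the 95th percentile (-1.27), but 87.8% of S-phase genes fell by more (list median -3.67). With 1687 genes at least 2-fold lower in PluriSIn#2, many genes of other kinds could lie inside that wide range too. The scalings tried do not test normalization: Usp37 was at -1.49 under the one that moved it most, but that scaling moved the median gene by only 0.07. The rule that leaves the scalings undecided, here and for respiratory chain and ribosomal protein genes, was set after their values were seen, and the criteria written without it argued against normalization. Whether Usp37 responds to the inhibitor directly or falls with other genes of dividing cells stays open, as division was not measured here.

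Respiratory chain genes rose and ribosomal protein genes fell, although both encode short transcripts. Exonic length here joined all annotated exons of a gene, with medians of 2.01 kb for respiratory chain and 1.78 kb for ribosomal protein genes. It can exceed the length of a transcript. Length by this measure is argued against for both. Random lists matched on it and on expression had medians of -0.066 (95% range -0.32 to 0.28) against 0.63, and of 0.11 (-0.11 to 0.36) against -0.66. An effect of the length of the transcripts themselves was not tested. The scalings tried do not test normalization, since they moved the median gene by at most 0.07 and left the list median nearest to 0 at -0.59. A lower demand for ribosomes in cells that divide less is a hypothesis that was not tested, and reads shared with pseudogenes stay open for the ribosomal proteins.

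Long genes might be expected to fall under a topoisomerase inhibitor. The 2127 genes spanning over 100 kb had a median log2 fold change of -0.0094, inside the range of random lists matched on expression (median 0.01, 95% range -0.03 to 0.05), with 890 rising and 925 falling. As a set, these long genes thus did not fall below genes of like expression. Whether some of them fell because of their span stays open, since members went both ways. Across 13878 genes, which are not independent replicates, span and log2 fold change had a Spearman correlation of -0.05. In 10 equal bins by span, the median log2 fold change was 0.109 in the shortest, -0.145 in bin 9 and 0.075 in bin 10, the longest. The cut at 100 kb falls within bin 9, so the pooled median joins bins that moved in opposite directions.

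The rise of Ttr could reflect choroid plexus epithelium in the treated cultures: of the 21 other measured choroid plexus genes 85.7% rose and 2 fell (median 3.02). The most abundant risers after Ttr were Slc4a2 (81.3 to 152 CPM), Ace (3.74 to 42.3 CPM) and Enpp2 (16.4 to 29.5 CPM), far below the 501 CPM of Ttr, and 5 members were above 10 CPM in DMSO already. Expression of these genes by neural cells stays open.

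The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 11915 genes, and the highest of the others called 0, so 1 of the 10 splits gave as many genes.

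Of the genes called by both edgeR on counts and limma on log2(FPKM + 1), 7 had opposite directions. The 2 differ in input, test and filter at once. Vps26b, for example, was at -0.10 by counts and 0.17 by FPKM, and Fam69a at -0.57 and 0.21. For Fam69a the gene length implied by the deposited values differed between groups by -0.73 on the log2 scale, so its direction depends on the length used.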
